A study of Homo sapiens with 6 samples.

How the data were processed

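RNA sequencing was done on 6 libraries made from total RNA of cells labelled Hep3B, a cell line derived from a human hepatocellular carcinoma. Cells were transfected with si-SNHG17-1, a small interfering RNA (siRNA) against the long noncoding RNA SNHG17, or with si-NC, the control siRNA. Each group had 3 libraries, and the group and replicate number of every library came from its title. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

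The authors deposited a single table of raw counts per gene, whole numbers that were not normalised. Reads were aligned with HISAT2 and the genome build was GRCh38, per the submitters' processing notes, which give no HISAT2 version. The counting program, the annotation release, the siRNA sequences and whether counting used strand are not given in the sources used here. The table holds 58243 genes under versioned Ensembl identifiers, each with the start and end of the whole gene. Matching without the version found 57980 of them in GENCODE release 29, and 55619 also had the same version, all of these with identical coordinates. Gene types, transcript lengths and 3′ UTRs were taken from that release, so they may differ from the annotation behind the counts.

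Checks of the deposited counts set limits on how they can be read. All 37 genes of the mitochondrial chromosome were listed at 0 in every library. Some genes moved together with an antisense partner, as TPM4 with AC008894.3 (log2 fold changes of 1.65 and 1.57), and others did not, as TGM2 with RPRD1B (0.28 and −0.13), so reads of overlapping genes on opposite strands may be mixed in part. Low counts that were multiples of 4 were 1.54 to 1.80 times as frequent as their neighbours. In each library 4 to 11 genes stood at 0 although both other replicates of the group had 50 counts or more. The values may therefore not be plain tallies of reads, and the count model below takes them as if they were. A gene sharing exons with another gene, or with near-identical copies, is uncertain for the same reason.

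Total counts were 38245838, 42271168 and 40351473 in the si-NC libraries and 37789407, 41620321 and 30207055 in the si-SNHG17-1 libraries. A floor of 3 counts corresponded to between 0.0710 and 0.0993 CPM, the unit of edgeR in which each library's counts are scaled to the same total, and such floors cover counting error only. No library pair within a group agreed within sampling noise (chi-square per degree of freedom of 24.6 to 50.4). No library was thus a copy of another, and all 6 were treated as separate samples. This measure cannot tell separate cultures from repeat libraries of the same culture.

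Groups were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 18679 genes. Library sizes were scaled with TMM, and the quasi-likelihood F test was run without a replicate block, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and a 2-fold call also needed an absolute log2 fold change of 1 or more. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled and given as mean ± SD, except for the cell identity markers, which are per total count.

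Before the data were examined, 34 gene lists with 1111 memberships were fixed, of which 1108 matched a gene of the table. Lists with at least 5 tested members were compared with all other genes by limma 3.58.1 camera on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 32 lists tested. The lists of mitochondrially encoded transcripts and of snoRNAs hosted by SNHG17 had no tested member. The rule for genes to name was also fixed then. It takes SNHG17, the 10 largest rises and 10 largest falls and the 5 smallest adjusted p in each direction, among called genes with at least 2 CPM in a group, a symbol other than a clone name and no overlap between groups. It adds from each list up to 2 called members per direction with the smallest adjusted p, or the most abundant member where none was called. This gave 111 genes. The text gives values mainly for the 65 called genes that kept their call in all 6 fits with a library left out, a choice made after the data were seen. The other 45 called genes lost the call in at least 1 of these fits, and those among the largest changes, or needed to describe a list, are given with that limit. Some genes that the rule names, 1 gene list and 1 test of cell identity are not reported here.

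Alternatives fixed before the data were examined were median-of-ratios size factors, total counts, no filter beyond a total above 0, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0 with its own filtering, limma-voom, a replicate block, each library left out in turn, camera with an estimated correlation and fry. Leaving out genes with the word TCAATC in their 3′ UTR was added after the data were seen. DESeq2 was first run on the genes kept by filterByExpr. After those counts were seen, it was run on all genes with a count, which is closer to the alternative as first worded, and the run on filtered genes is kept as an added alternative.

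The edgeR step was tested on simulated counts for this comparison, with the real means, dispersions and library sizes and 200 changed genes among 18140 genes. It called 8 of 65 genes changed 1.5-fold (12.3%), 45 of 64 changed 2-fold (70.3%) and 68 of 71 changed 4-fold (95.8%). There were also 11 false calls, so the false share of calls was above the nominal 0.05 in this simulation. The changed genes all had a mean of at least 2 CPM. The data gave 1954 calls, and the excess of multiples of 4 was not simulated, so these rates may not carry over. On counts simulated the same way, camera called the 1 list that was shifted 1.5-fold and none of the others. Genes were drawn independently there, so the preset inter-gene correlation was not tested.

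For the word test, the longest annotated 3′ UTR of each protein-coding gene with at least 2 CPM in a group and a UTR of at least 50 bases was searched, in 12006 genes. For every 7-base word present in at least 100 genes, log2 fold change was regressed on its presence with UTR length and GC content as covariates. The lowest t was compared with the lowest in 100 shufflings of the fold changes. In simulated data with a word planted as repressive in 828 of the 12006 genes, that word was recovered as the lowest of all. A single effect size was planted, so recovery of words with weaker effects was not tested. The words were also chosen in a random 6003 of the genes, and the site built from the 2 lowest was tested in the other 6003 by regression with the same covariates. For the length and GC tests, a spline with 5 degrees of freedom was fitted to log2 fold change against the longest transcript's length or GC content, outside the list tested, and removed from every gene.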

Results

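The transcriptomes of cells labelled Hep3B were compared after transfection with si-SNHG17-1 or with the control siRNA si-NC, 3 libraries per group. The question was which genes change when SNHG17, a long noncoding RNA that hosts small nucleolar RNAs, is lowered. Total counts ranged from 30207055 to 42271168 per library. Correlations of log2 CPM between libraries were 0.966 to 0.973 within groups and 0.953 to 0.965 between groups. The first principal component (32.8% of variance) separated the groups, the second (19.1%) set si-NC replicate 1 apart from si-NC replicates 2 and 3, and the third (18.2%) set si-SNHG17-1 replicate 3 apart from si-SNHG17-1 replicates 1 and 2.

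SNHG17 was lower in all 3 si-SNHG17-1 libraries than in any si-NC library. Its counts were 843, 953 and 948 in si-NC and 307, 338 and 254 in si-SNHG17-1. In CPM it fell from 23.0 ± 0.789 to 8.11 ± 0.139 (SD, n = 3 each), leaving 35.2% ± 0.605 of the control level. The log2 fold change was −1.51 with a standard error of 0.12 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00101). An exact two-sided permutation test of this gene gave p = 0.1, the smallest value that 3 against 3 libraries allow. SNHG17 (ENSG00000196756.11) lies on chromosome 20 from 38420588 to 38435353 of GRCh38, on the minus strand, and its exons overlap SNORA71. Among called genes 42 fell by more than SNHG17.

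**Figure D1:**
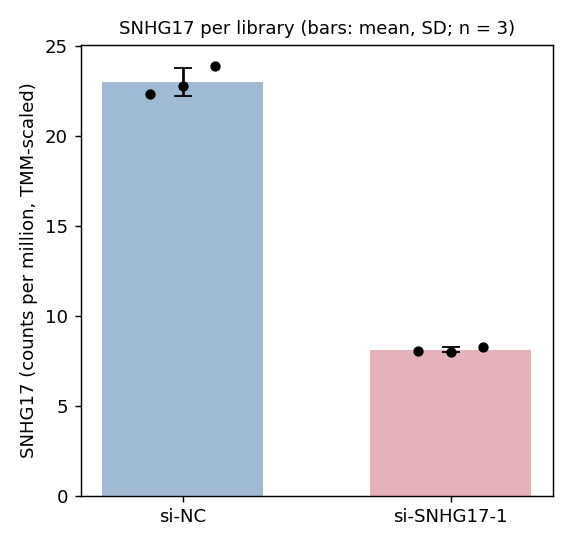
SNHG17 in CPM (vertical axis) for each library (points), with the group mean and SD as bar and whisker for si-NC and si-SNHG17-1. The si-SNHG17-1 libraries average 8.11 and the si-NC libraries 23.0.

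Hep3B cells are known to secrete alpha-fetoprotein and albumin. AFP, which encodes alpha-fetoprotein, did not exceed 0.216 CPM in any library, and ALB, which encodes albumin, ranged from 0.157 to 0.820 CPM. The apolipoprotein genes APOA1 and APOB stayed at or below 0.284 and 0.941 CPM. TTR and GPC3 had 0 counts in every library, which allows up to 0.0993 CPM at the lowest depth. For comparison, GAPDH was present at 4252 to 5802 CPM. Of 55 hepatocyte secreted protein genes, 41 were under 1 CPM, as were 36 of 51 genes of hepatocyte metabolism and nuclear receptors. Other members were abundant, such as C3 at 386.9 CPM and ASS1 at 437.5 CPM in si-NC (means of TMM-scaled values). The cells are therefore called here by their label, and the single markers were chosen after their values were seen.

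**Figure D2:**
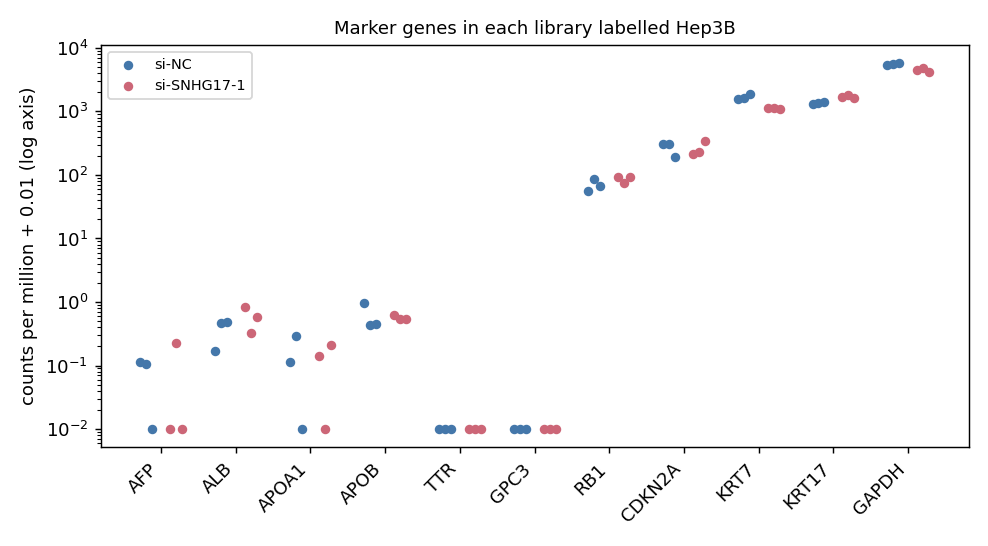
CPM plus 0.01 (log axis) of 11 marker genes in the 6 libraries, each point a library, coloured by group. The liver genes AFP, ALB, APOA1, APOB, TTR and GPC3 stay below 1 CPM in every library, and GAPDH does not fall below 4252 CPM.

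After si-SNHG17-1, 980 genes were higher and 974 lower of 18679 tested with TMM scaling, and 1168 were higher and 781 lower with total counts only. TPM4, an actin-binding tropomyosin, GANAB, the catalytic subunit of glucosidase II, and PTGS2, the inducible cyclooxygenase, rose 3.15-fold, 2.93-fold and 3.03-fold. BASP1, a membrane-bound signalling protein, and ERH, a small nuclear protein, fell 2.59-fold and 4.07-fold. At 2-fold or more, 225 genes were higher and 129 lower. The median absolute log2 fold change of called genes was 0.61, so most calls were smaller than 2-fold. The counts of calls fell whichever library was left out, and fewer libraries leave less to test with. Without si-SNHG17-1 replicate 1 there were 313 higher and 264 lower genes, without replicate 2 there were 402 and 366, and without replicate 3 there were 399 and 332. Without si-NC replicate 1 there were 694 and 705, without si-NC replicate 2 there were 616 and 578, and without si-NC replicate 3 there were 527 and 531. At 2-fold or more, the higher genes numbered 129, 138 and 128 without si-SNHG17-1 replicates 1, 2 and 3, and the lower genes 68 and 77 without replicates 1 and 3.

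TPM4 (ENSG00000167460.14, chromosome 19, 16067021 to 16103005) rose from 409 ± 7.10 to 1289 ± 45.1 CPM, with a log2 fold change of 1.65 and a standard error of 0.05 (edgeR adjusted p = 6.745e-05). GANAB rose from 206 to 602 CPM (log2 fold change 1.55 ± 0.07 SE), and PTGS2 from 37.0 to 112 CPM (1.60 ± 0.08 SE). TNFRSF14 (ENSG00000157873.17, chromosome 1, 2555639 to 2565382), a receptor for the cytokine LIGHT, had the largest rise among the named genes with counts in both groups, from 4.39 ± 0.597 to 41.0 ± 6.60 CPM (log2 fold change 3.22 ± 0.18 SE, edgeR adjusted p = 0.00033). Its antisense partner TNFRSF14-AS1 rose with it (2.48 ± 0.18 SE), and their reads may be mixed. AREG, which encodes the EGF receptor ligand amphiregulin, rose from 5.31 to 24.5 CPM (2.21 ± 0.13 SE). In addition, NRIP3, PACSIN1 and ZNF724 rose by 2.89, 2.28 and 2.24 on the log2 scale. The read-through gene BORCS7-ASMT was at 0 counts in all si-NC libraries and at 86, 94 and 88 in si-SNHG17-1, at least 32.3-fold higher against a floor of 3 counts per library. Its overlapping partner AS3MT went the other way, from 77, 58 and 92 counts to 0, so this gain is uncertain. Rises of BHLHB9, HMCN1 and ZNF624, by 2.34, 2.18 and 2.13 on the log2 scale, lost the edgeR call in 5 of 6 fits with a library left out, at adjusted p up to 0.120 (without si-SNHG17-1 replicate 3), 0.125 (without si-SNHG17-1 replicate 3) and 0.0905 (without si-NC replicate 3). Among these fits BHLHB9 kept its call only without si-SNHG17-1 replicate 1, HMCN1 only without si-NC replicate 3 and ZNF624 only without si-SNHG17-1 replicate 2.

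TSPAN6 (ENSG00000000003.14, chromosome X, 100627109 to 100639991), a tetraspanin, had the largest fall among the named genes, from 46.4 ± 8.47 to 5.39 ± 1.25 CPM (log2 fold change −3.10 ± 0.22 SE, edgeR adjusted p = 0.000615). TBCA, a tubulin-folding cofactor, fell from 101 to 20.8 CPM (−2.28 ± 0.12 SE). ROBO1, the SLIT receptor, fell from 183 to 40.1 CPM (−2.19 ± 0.15 SE). ERH fell from 137 to 33.6 CPM (−2.02 ± 0.09 SE), and GFM2 from 70.9 to 25.1 CPM (−1.50 ± 0.09 SE). BASP1 went from 1419 to 547 CPM (−1.37 ± 0.06 SE). The noncoding RNAs MIR31HG and RN7SK were lower, with log2 fold changes of −2.16 and −2.14, and ANKRD2 fell by 1.86. IFNWP19, which fell by 2.52, shares exonic sequence with MIR31HG. AKR1C2, which fell by 1.96, and LGALS9B, which fell by 2.57, have near-identical paralogs, and RN7SK has many copies. The longest annotated 3′ UTR of TSPAN6, ROBO1 and GFM2 contained the 8-base word TTCAATCA, that of ERH contained TTCAATC and that of TBCA its core TCAATC. Those of BASP1, AKR1C2, LGALS9B and ANKRD2 did not contain the core, which 19.7% of all searched genes held. With a library left out, LGALS9B kept the edgeR call only without si-NC replicate 3, and its adjusted p reached 0.0873 without si-SNHG17-1 replicate 2. Exons of ERH overlap SLC39A9, those of GFM2 overlap NSA2 and those of BASP1 overlap AC026790.1.

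**Figure D3:**
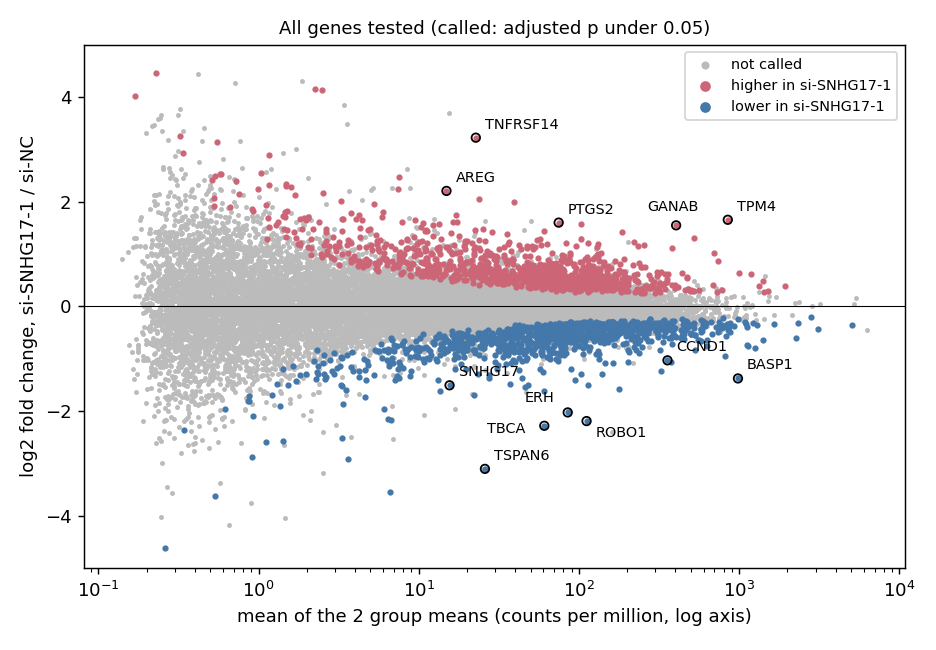
Log2 fold change between si-SNHG17-1 and si-NC (vertical axis) against mean CPM (log axis) for the genes tested. Called genes are coloured by direction, selected genes are circled, and 18 genes lie outside the plotted range of 5 in either direction. SNHG17 sits at −1.51 and TNFRSF14 at 3.22.

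Cytosolic ribosomal protein genes and the list of ribosome biogenesis genes and MYC targets were lower than the other genes by limma camera with the preset correlation (adjusted p = 2.465e-19 and 1.387e-06), but not with an estimated correlation (0.484 and 0.0529). Of 78 cytosolic ribosomal protein genes, 47 fell and none rose, and all 78 had a negative log2 fold change, also with the other scalings of the libraries, with a median of −0.34. RPL26 fell from 593 ± 13.6 to 413 ± 8.16 CPM (log2 fold change −0.52 ± 0.06 SE) and RPL7A from 667 to 494 CPM (−0.43 ± 0.05 SE). Of 42 ribosome biogenesis genes and MYC targets, 14 fell and none rose, with a median of −0.33. Among them were DDX21, a nucleolar RNA helicase (−0.83 ± 0.08 SE), and POLR1C, a subunit of RNA polymerases I and III (−0.85 ± 0.10 SE). Adjusted over the list alone, 66 ribosomal protein genes fell, and 21 biogenesis genes fell while 1 rose. Exons of POLR1C overlap XPO5, LRRC73 and YIPF3, and its 3′ UTR contained TCAATCA.

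NRF2 target genes, which serve antioxidant defence and detoxification, were the list with the lowest median. Of 26 tested, 16 fell and none rose, with a median log2 fold change of −0.52. AKR1C2 belongs to it, as does the efflux transporter ABCC3, which went from 276 ± 14.2 to 132 ± 5.12 CPM (−1.07 ± 0.07 SE). Adjusted over the list alone, 19 fell and 2 rose. The camera adjusted p was 6.597e-09, and 0.0529 with an estimated correlation. Nuclear genes of respiratory complex I and ATP synthase were also lower as a list by camera with the preset correlation (adjusted p = 0.00185), but not with an estimated correlation (0.553) or by fry (0.0665). The median was −0.20, although only 5 of 49 fell and 1 rose (7 and 1 adjusted over the list alone). ATP5J2 and ATP5C1 were lower, with log2 fold changes of −0.76 and −0.43. ATP5J2 lost the edgeR call without si-SNHG17-1 replicates 1 or 3 (adjusted p up to 0.0624) and ATP5C1 without any of the si-SNHG17-1 replicates (up to 0.0543). The 3′ UTR of ATP5J2 held the core TCAATC.

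Genes of DNA replication and of the endoplasmic reticulum unfolded protein response were higher as lists by camera with the preset correlation (adjusted p = 0.00144 and 0.00811), but not with an estimated correlation (0.116 and 0.297). Of 45 genes of DNA replication and S-phase entry, 5 rose and 1 fell, with a median log2 fold change of 0.16. RRM2, the small subunit of ribonucleotide reductase, rose from 68.9 ± 10.4 to 159 ± 20.9 CPM (1.20 ± 0.14 SE), and the transcription factor E2F1 rose from 51.6 to 84.1 CPM (0.70 ± 0.08 SE). CDC25A fell by 0.64 on the log2 scale, held TCAATCA in its 3′ UTR and, with a library left out, kept the edgeR call only without si-NC replicate 1 (adjusted p up to 0.101, without si-SNHG17-1 replicate 3). Of 26 genes of the endoplasmic reticulum unfolded protein response, 6 rose and 1 fell, with a median of 0.24. The chaperone CALR rose from 932 ± 2.22 to 1440 ± 123 CPM (0.63 ± 0.07 SE) and the disulfide isomerase PDIA4 from 254 to 399 CPM (0.65 ± 0.07 SE). DERL2 fell by 0.78, held TTCAATCA in its 3′ UTR, and lost the edgeR call without si-SNHG17-1 replicate 1 (adjusted p = 0.0534). Adjusted over the list alone, 11 replication genes rose and 1 fell, and 11 unfolded protein response genes rose and 2 fell.

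**Figure D4:**
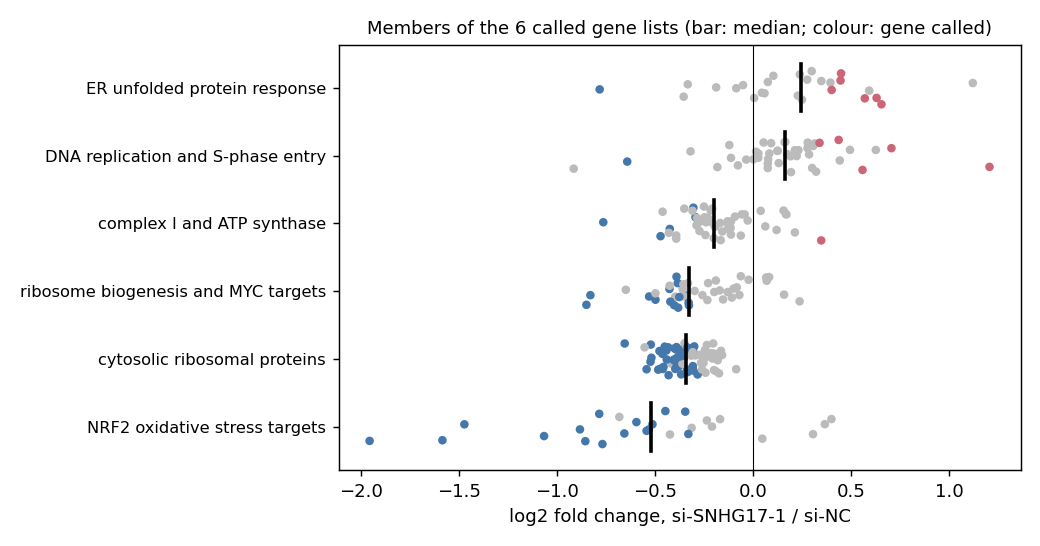
Log2 fold change between si-SNHG17-1 and si-NC of the members of the 6 gene lists called by camera with a preset correlation. Each point is a gene (red, called higher; blue, called lower; grey, not called) and the bar is the list's median, which runs from −0.52 for NRF2 targets to 0.24 for the unfolded protein response.

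Stress and signalling lists held changes in both directions and were not called by camera with the preset correlation, while fry called the NF-kB list higher (fry adjusted p = 0.00141). Of 40 ATF4 and integrated stress response genes, 6 rose and 13 fell (9 and 20 adjusted over the list alone; camera adjusted p = 0.0604). The pseudokinase TRIB3 and the stress sensor SESN2 rose by 1.24 and 1.26 on the log2 scale, while the amino acid transporter SLC7A5 and VLDLR were lower (−0.61 and −1.12). Of 47 interferon response genes, 1 rose and 8 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.0667), with OASL and ISG15 lower by log2 fold changes of −1.07 and −0.76. Of 28 NF-kB and cytokine genes, 7 rose and 2 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.234). The cytokine gene IL6 rose from 90.7 to 184 CPM, and TNFAIP2 fell from 264 to 145 CPM. Of 36 hypoxia and glycolysis genes, 3 rose and 9 fell (4 and 14 adjusted over the list alone; camera adjusted p = 0.0604). PFKL rose by 0.57, and GAPDH fell by 0.34 but lost the edgeR call without si-SNHG17-1 replicate 1 (adjusted p = 0.0650). The interferon list was called lower without si-NC replicate 3 or si-SNHG17-1 replicate 1 (camera adjusted p = 0.0223 and 0.0415), as was the hypoxia list without si-NC replicate 2 (0.0207). OASL and SLC7A5 held TCAATCA in their 3′ UTRs.

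Growth factor and adhesion genes likewise moved both ways. None of these lists was called by camera with the preset correlation, while fry called YAP and TEAD targets and MAPK genes higher and epithelial junction genes lower (fry adjusted p = 0.00284, 0.0400 and 0.0251). CCND1, which encodes cyclin D1, fell from 479 ± 16.4 to 235 ± 6.18 CPM (log2 fold change −1.03 ± 0.06 SE, edgeR adjusted p = 0.000413). Of 35 MAPK and immediate early genes, 7 rose and 4 fell (8 and 8 adjusted over the list alone; camera adjusted p = 0.568), with DUSP5 among the rises (0.75). Of 24 YAP and TEAD targets, 4 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.265). CYR61 rose from 528 to 958 CPM and LATS2 rose from 57.9 to 117 CPM, while CRIM1, with TTCAATCA in its 3′ UTR, fell from 411 to 231 CPM. Of 44 mesenchymal and migration genes, 9 rose and 4 fell (12 and 6 adjusted over the list alone; camera adjusted p = 0.383). THBS1, which encodes thrombospondin 1, and the transcription factor SNAI2 rose by 1.20 and 1.10, and the epithelial adhesion genes LAMB3 and ITGB4 were lower (−0.57 and −0.89). In that list the median was −0.00 and the mean 0.16, and the test's direction was up. Of 20 TGF-beta targets, 3 rose, CTGF among them (0.80), and none fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.327). Of 14 Wnt targets, TBX3 rose by 0.77 and CCND1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.907), with a median of 0.05 and a mean of −0.09, and the test's direction was up. Of 27 epithelial junction genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.214).

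Lists of mitosis, histone, apoptosis and RNA interference genes were not called by camera. Of 48 mitosis genes, 2 rose and 4 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.739), and MYBL2 and BIRC5 rose by 0.57 and 0.76. Of 30 replication-dependent histone genes, 5 rose and none fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.214). The median log2 fold change was 0.42 and the mean 0.10. Of the 42 matched members of this list, 24 were under 1 CPM. HIST1H2BJ rose from 1.94 to 6.51 CPM. Of 34 apoptosis regulators, 3 rose and 1 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.739). Of 13 RNA interference genes, 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.705).

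Metabolic and liver lists were not called by camera with the preset correlation. Fry called hepatocyte metabolism, fatty acid synthesis and fatty acid oxidation lower (fry adjusted p = 0.0143, 0.0188 and 0.0299). Of 25 cholesterol synthesis genes 2 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.539). Of 23 fatty acid synthesis genes 1 rose and 5 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.214), and FASN, the fatty acid synthase gene, went from 797 to 557 CPM. Of 23 fatty acid oxidation genes 1 rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.0620). PDK4, a kinase that inhibits pyruvate dehydrogenase, rose from 11.6 to 27.5 CPM, and HSD17B4 fell from 129 to 82.8 CPM. Only 21 hepatocyte metabolism genes could be tested, of which none rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.0580), including ASS1 (−0.61). This list was called lower without si-NC replicate 1 (0.0298) or without si-SNHG17-1 replicate 1 (0.0428, both camera adjusted p). Of 23 hepatocyte secreted protein genes 2 rose, CFB and AGT (0.58 and 1.62), and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.523). Of 18 oncofetal and liver cancer markers 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.283). Those that fell were KRT7 (from 1721 to 1100 CPM) and the imprinted noncoding RNA H19 (from 1419 to 842 CPM).

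Around SNHG17 itself, none of the 6 hosted or neighbouring snoRNAs in the table passed the expression filter. Of 14 neighbouring genes on chromosome 20, 11 had a negative log2 fold change, with a median of −0.14. By call, 1 rose and none fell (none adjusted over the list alone, camera adjusted p = 0.234). The rise was that of TGM2 (0.28), a gene with TCAATC in its 3′ UTR, which lost the edgeR call whichever library was left out (adjusted p up to 0.132). Of 26 other small nucleolar RNA host genes, 1 rose and 4 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.459). The rise of SNHG12 (0.58) and the falls of GAS5 (−0.38) and SNHG14 (−0.52) each lost the edgeR call without any one of the si-SNHG17-1 replicates (adjusted p up to 0.123, 0.0731 and 0.0959). SNHG12 and SNHG14 also lost it without si-NC replicates 2 or 3.

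Markers of other cell types were mostly low. Of 8 fibroblast markers tested, 2 rose, COL3A1 and COL1A1 (0.52 and 0.36; 3 and 0 adjusted over the list alone; camera adjusted p = 0.539), and both lost the edgeR call without any one of the si-SNHG17-1 replicates (adjusted p up to 0.0624 and 0.138). COL1A1, whose 3′ UTR held TCAATC, also lost it without any one of the si-NC replicates. Of 5 endothelial markers, CDH5 rose from 1.70 to 5.89 CPM (1 adjusted over the list alone; camera adjusted p = 0.534), a call lost without si-SNHG17-1 replicates 1 or 2 (edgeR adjusted p up to 0.0630). None of 6 blood cell markers passed the test (2 higher adjusted over the list alone; camera adjusted p = 0.907), where the median was −0.02, the mean −0.22 and the test's direction up. The most abundant, CD68, was at 34.9 and 50.4 CPM (edgeR adjusted p = 0.0635).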

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

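Leaving out genes with TCAATC in the 3′ UTR, and DESeq2 after filterByExpr, were chosen after the result was seen. SNHG17 was lower and called under all 15 alternatives, with log2 fold changes from −1.53 to −1.47 and adjusted p from 1.368e-25 (DESeq2 after filterByExpr) to 0.0238 (replicate block). No named gene reversed under any of them. Of 666 values with a library left out, 165 lost the call, as did 19 of 867 under the other scalings, filters and tests, 14 of these with no filter beyond a total above 0, where p is adjusted over 30186 genes. The cause of the other changes was not tested, except that fewer libraries leave less to test with. Leaving out each library gave 313 to 694 higher and 264 to 705 lower genes, and 128 to 210 higher and 68 to 98 lower at 2-fold or more. It gave 2 lists higher and 4 to 6 lower, against 2 and 4 with all libraries. With no filter, 627 genes were lower. Total counts in place of TMM gave 1168 higher and 781 lower genes (59.9% higher, against 50.2%), so the near-even split depends on the scaling. DESeq2 called 1592 higher and 1568 lower genes after filterByExpr, over 1.5 times the edgeR counts, and 1424 and 1395 among all genes with a count, within 1.5 times. Without genes holding TCAATC in the 3′ UTR, 807 genes were higher and 749 lower, and 7 lists were lower. With an estimated correlation camera called 0 lists higher and 0 lower. The directional test of fry asks only whether a list moves on balance, against no change rather than against the other genes. It called 5 and 7, without complex I and ATP synthase (fry adjusted p = 0.0665). The mixed test of fry, which allows changes in both directions, called 31 of 32 lists. All 78 ribosomal protein genes stayed below 0 with median-of-ratios size factors and with total counts.

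Replicate numbers are shared between the groups, but same-numbered libraries did not deviate together (correlations of −0.02, −0.04 and −0.02). With the replicate number as a block, 273 genes were higher and 259 lower, 113 and 69 of them at 2-fold or more. In that blocked fit 40 named genes lost the call, and no library correlated best with its own number.

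Depth limits what can be said of low genes, since the floor of 3 counts lies between 0.0710 and 0.0993 CPM.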

Other observations

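Tests of the liver markers, the sites of the words below in genes not used to choose them, the fit with added dinucleotide covariates and the words with the highest fold changes were chosen only after the result was seen.

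Several other genes, some of them genes of other epithelia, were abundant in these libraries, chosen here after their values were seen. KRT7 ranged from 1074 to 1863 CPM, KRT17 from 1303 to 1790 CPM and ALPI, which has near-identical paralogs, from 1521 to 2330 CPM. The keratin genes KRT8 and KRT18 were also present, at 517 to 615 CPM and 209 to 328 CPM. CDKN2A, which encodes the p16 inhibitor and is lost in many cell lines, was at 190 to 342 CPM, and RB1 at 55.1 to 93.5 CPM.

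Genes that fell by at least 2-fold were examined for siRNA seed effects, the repression of mRNAs whose 3′ UTR pairs with the first bases of an siRNA strand. Of 15925 words of 7 bases, TCAATCA went with the lowest fold changes (t = −13.3, against −4.87 for the lowest in 100 shufflings; −13.0 with dinucleotide composition as covariates), followed by TTCAATC (t = −11.0). When words were chosen in a random 6003 of the searched genes, the same words were lowest. In the other 6003 the regression coefficient against genes without the core TCAATC was −0.30 (SE 0.03) for TTCAATCA and −0.09 (SE 0.02) for the core only. Of the 79 searched genes lower at least 2-fold, 39 held the core (49.4%) and 40 did not, against 19.7% of all searched genes with it. These shares are not adjusted for UTR length, and the words were chosen with these genes included. The prediction set beforehand also asked that the lowest word itself occur in SNHG17, and it was not met, since TCAATCA is absent from both strands. TTCAATC, the next lowest word, occurs in the last exon of 5 of 8 annotated transcripts (chromosome 20, 38420777 to 38420783). This is weak evidence because 20.2% of all words occur in SNHG17 and 33.7% on either strand. The 2 words share the core TCAATC, so the absence of TCAATCA alone does not argue against a seed that pairs with TTCAATC. The word test alone thus leaves seed repression by si-SNHG17-1 open, since the siRNA sequence is not given, while the lower coefficient of the longer site, in genes not used to choose it, is consistent with it, as a hypothesis. Splitting of reads between overlapping genes is argued against only for the 40 genes that fell at least 2-fold and overlap no other. For the other falls it stays open, since the share overlapping another gene, 69.0%, was close to the 71.4% of all tested genes. Other causes of these falls also stay open, a response to SNHG17 loss included.

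At the other end of the same test, GGAGAAA (t = 5.99) and TCGGAGA (t = 5.50) went with the highest fold changes, against 5.00 for the highest in the shufflings. Seed effects of si-NC, whose absence from the si-SNHG17-1 libraries would appear as rises, are left open, since its sequence is not given.

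Cytosolic ribosomal protein genes were lower together, with a median log2 fold change of −0.34. Biases between libraries tied to the length or GC content of the longest annotated transcript are argued against. The median was −0.35 after either trend was removed (SD over the 78 genes 0.11 each), with camera adjusted p = 2.946e-18 and 3.597e-19 at the preset correlation. The longest annotated transcript (list median 1841.5 bases) may not be the expressed one. A bias tied to the length or GC content of the expressed transcripts therefore stays open. Without removal of a trend, the list was not called with an estimated correlation (0.484). A response to lower SNHG17, to the siRNA sequence itself or to differences in culture may remain, and these were not separated by the design, which used a single siRNA.

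The liver marker genes AFP, ALB, APOA1, APOB, TTR and GPC3 were below 1 CPM in libraries labelled Hep3B. In the fixed hepatocyte lists, 41 of 55 and 36 of 51 genes were under 1 CPM, but other members were abundant. Among these were C3 (386.9 CPM in si-NC and 286.3 in si-SNHG17-1) and ASS1 (437.5 and 286.9 CPM). Low depth is argued against by the floor of 3 counts, at or under 0.0993 CPM, for genes expressed well above it. That AFP and ALB did not exceed 0.820 CPM in any library restates the pattern. A failure to count these genes was not tested. If these counts hold, AFP at or below 0.216 CPM and ALB at or below 0.820 CPM argue against cells that secrete both proteins. Hep3B cells are known to do so. Which cells were sequenced stays open, and no biological explanation was tested, because all 6 libraries carry the same cell label.

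The numbers of called genes were set against other splits of the 6 libraries into 3 and 3. The real split gave 980 higher and 974 lower genes (313 to 694 and 264 to 705 with a library left out), 1 of 10 splits with that many, and the most that any other split gave in a direction was 1. With 10 splits no share under 0.05 can be reached.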
